A study of Drosophila melanogaster with 3 samples.

How the data were processed

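Ovarian small RNAs were sequenced from 3 Drosophila melanogaster strains, 1 library each. Per the labels' protocols, RNA was isolated with Trizol from adult flies kept at a constant temperature on standard food. Small RNAs of 23 to 29 nt were cut from a polyacrylamide gel, adapters were ligated to both ends, and the products were amplified by PCR, gel purified and multiplexed. The gel cut leaves out shorter small RNAs such as siRNAs, so the profile starts at the lower edge of the cut by construction. The aligner, the trimming steps, the mapping parameters and the Penelope reference sequence are not given in the sources used here.

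The deposited tables list small RNA sequences that match Penelope, with raw read counts per distinct sequence that the authors did not normalise, as far as the file headers show. Per the file headers each line gives the sequence, flags for T at base 1 and A at base 10, the count, the strand, the start and end on Penelope, the length and the mismatches. The flags and lengths were checked against the sequences and matched on every line. The lists held sequences of 23 to 30 nt with at most 2 mismatches and named 1 target. The end minus the start equalled the length, and mismatch positions count from 0, so the coordinates were read as half-open and are printed here counted from 1. Of the lines, 5 were empty, 3 in A1a and 2 in A2d, and were not analysed here.

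A sequence that matches at more than 1 place is listed with its full count at each place, which applied to 257 sequences in A1a, 537 in A2d and 63 in A2h. Summing over lines would give 2413, 5235 and 838 reads. Each sequence was therefore counted once, which left 1777, 3870 and 748 reads. For profiles along the element its count was divided equally between its places. The Penelope sequence was rebuilt by replacing each listed mismatch with the reference base and placing the reads on the element. No position received contradictory bases, and the read base of every mismatch equalled the base in the sequence. Terminal repeats were taken as the span of sequences with more than 1 place, and the reading frame as the longest one from ATG on the plus strand. The host genome annotation was not used here, since all coordinates are on the element.

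Depth limits the values of A2h most. Its 45 sense reads give the widest intervals. Most sequences were seen a single time: 74.5% of the sequences of A1a, 71.8% of A2d and 78.7% of A2h. The highest count of any sequence was 42, 102 and 18. Shares are given with exact (Clopper-Pearson) 95% binomial intervals on reads, which cover counting error only. A count of 0 was taken to allow up to 3 counts.

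Before the data were examined, each strain was set as its own group with 1 library, so that no test between strains was planned. No p-value between strains was computed. Draws of A1a and A2d set against A2h, and its sense mismatches set against theirs, were added later and compare single libraries. The readouts fixed before examination were read totals, length profile, strand, bases 1 and 10, 5′-to-5′ overlaps, position profile and shared sequences. The named items were fixed at the same time as the 5 most abundant sequences of each library, sequences among the 20 most abundant of all 3 libraries, and the 3 strongest bins of 100 nt per strand and library. Gene lists and cell type markers had been set for tables of features and were not applied to lists that hold a single element. The background for a base was its share at all other read positions, leaving out bases 1 and 10, in the reads of the same strand.

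The overlap score is the number of sense-antisense read pairs at 10 nt, each pair of sequences counted once and weighted by the product of the counts, minus the mean over the other overlaps from 1 to 20 nt, divided by their SD. A similar score described distances from the 3′ end of a read to the 5′ end of the next on the same strand, for distances of 1 to 20 nt, with the smaller of the end counts summed over positions. Both scores were tested on simulated data, with 1500 random reads on an element of this length. Without added structure they were -0.28 and -0.23, with 200 added pairs of 10 nt overlap the first was 8.70, and with 150 added trains of antisense reads laid head to tail the second was 16.9. The random reads were spread evenly over element and strands, each with a count of 1 and without repeats. The simulation therefore does not show what score clustered or unevenly counted reads without pairing would give. Shared sequences were compared after thinning to 748 reads in 200 draws.

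Alternatives fixed before the data were examined were counting each distinct sequence once, keeping sequences with 2 or more reads, keeping 23 to 29 nt, leaving out the most abundant sequence, accepting overlaps of 9 to 11 nt, bins of 50 and 200 nt, comparing the first 20 nt, and lists without thinning. Added after seeing the data were exact matches only, sequences with 1 place only, leaving out the strongest antisense bin, and thinning A1a and A2d to the strand totals and to the read total of A2h. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.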

Results

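Small RNAs of ovaries that match the retroelement Penelope were listed for 3 Drosophila melanogaster strains, named A1a, A2d and A2h, with 1 library per strain. Penelope is a retroelement known from Drosophila virilis, where its mobilisation accompanies hybrid dysgenesis, and it encodes a reverse transcriptase joined to a GIY-YIG endonuclease. piRNAs are small RNAs of the germline and its supporting cells that guide Piwi proteins to transposon transcripts. The libraries were made from RNA of the piRNA size range, and the strains were ones in which Penelope piRNAs had been seen on Northern blots. The lists held 1777 reads of 970 distinct sequences in A1a, 3870 reads of 1800 sequences in A2d and 748 reads of 474 sequences in A2h. Since the strains had no replicate libraries, no test between strains was possible. Ranges in brackets after a share are, unless said otherwise, exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only. The reads were amplified by PCR without molecular identifiers and are not independent molecules, so the intervals are too narrow by an unknown amount. No total of all small RNAs per library was used here. The read numbers therefore cannot tell sequencing depth from the abundance of Penelope piRNAs in a strain, and depth here means the number of listed reads.

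The listed matches spanned positions 3 to 3399 of the authors' Penelope sequence, whose accession is not given in the sources used here. Of these positions, 88 were covered by no read. Sequences that matched at more than 1 place marked a pair of directly repeated ends, at positions 3 to 618 and 2784 to 3399. The longest open reading frame of the sequence rebuilt from the matches ran from position 617 to 3190, with 857 codons before the stop. Within that frame 46 positions had no read, so a stop codon there would not have been seen. The plus strand was rich in A, at 42.9% of covered positions, against 21.6% T.

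The size profile, the question the series names, had a single peak at 25 or 26 nt in all 3 libraries, within the 23 to 29 nt selected on the gel. Reads of 25 nt were the most frequent in A1a (24.4%, interval 22.4 to 26.4%) and in A2d (24.03%, 22.7 to 25.4%), and reads of 26 nt in A2h (24.9%, 21.8 to 28.1%). Mean length was 25.8 ± 1.58 nt (SD over 1777 reads) in A1a, 25.99 ± 1.53 nt (SD over 3870 reads) in A2d and 26.004 ± 1.64 nt (SD over 748 reads) in A2h. Reads of 24 to 26 nt made up 63.4% (61.1 to 65.6%), 62.7% (61.1 to 64.2%) and 57.8% (54.1 to 61.3%) of the A1a, A2d and A2h lists, in that order. The interval of A2h overlapped those of the other libraries. Sense and antisense reads had mean lengths within 0.3 nt of each other in A1a and A2d. In A2h the sense reads averaged 24.8 ± 1.95 nt (SD over 45 reads) against 26.1 ± 1.59 nt (SD over 703 reads) for antisense reads. Of the A2h sense reads, 37.8% (23.8 to 53.5%) were 23 nt long, against 3.81% (2.56 to 5.42%) of the A1a sense reads and 1.31% (0.804 to 2.02%) of the A2d sense reads.

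**Figure D1:**
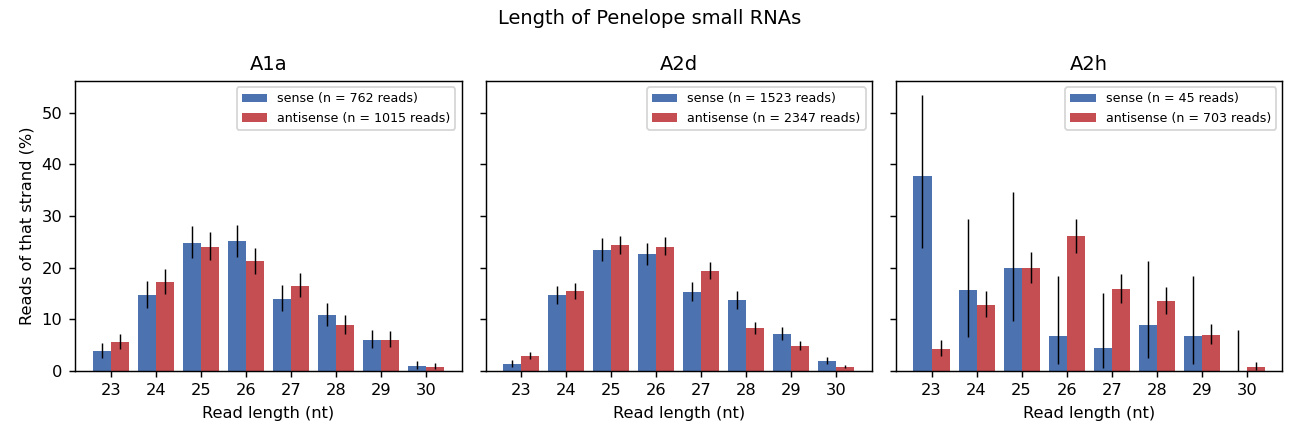
Share of reads at each length from 23 to 30 nt (vertical axis, percent of the reads of that strand) for sense and antisense Penelope small RNAs in the 3 strains, with exact 95% binomial intervals as bars. A1a and A2d peak at 25 to 26 nt on both strands, while the 45 sense reads of A2h are most frequent at 23 nt.

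The libraries, 1 per strain, differed in the strand of their Penelope small RNAs. Antisense reads, which are complementary to the element's transcript, made up 57.1% (54.8 to 59.4%) of the reads in A1a and 60.6% (59.1 to 62.2%) in A2d. In A2h they made up 94.0% (92.03 to 95.6%), with 703 antisense and 45 sense reads. The interval of A2h lay far from both others, whereas those of A1a and A2d overlapped by a small margin. Restricted to sequences with 1 place on the element, the antisense shares were 53.4%, 55.2% and 97.1% in A1a, A2d and A2h. Of the A2h sense reads, 48.9% (33.7 to 64.2%) matched with a mismatch, against 31.1% (27.8 to 34.5%) in A1a and 25.0% (22.9 to 27.3%) in A2d, where the interval of A1a overlaps that of A2h. Leaving out position 580, where nearly all reads of every library differed from the authors' sequence, and its copy at 3361, a choice made after seeing the data, 40.0% (25.7 to 55.7%) of them carried a mismatch. The corresponding shares were 11.2% (9.01 to 13.6%) in A1a sense reads, 11.8% (10.2 to 13.5%) in A2d sense reads and 8.82% (6.83 to 11.2%) in A2h antisense reads.

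Uridine at the first base, the signature of primary piRNAs, was frequent on both strands of every library. Among antisense reads it reached 73.3% (70.5 to 76.0%) in A1a, 79.8% (78.1 to 81.4%) in A2d and 81.5% (78.4 to 84.3%) in A2h. The share of U at the other positions of the same reads, leaving out bases 1 and 10, was 32.8%, 38.03% and 36.0%. Among sense reads the first base was U in 60.5% (56.9 to 64.0%) in A1a, 55.7% (53.1 to 58.2%) in A2d and 57.8% (42.2 to 72.3%) in A2h. The background of U within sense reads was lower, at 18.8%, 18.6% and 19.5%, so the excess at the first base was 41.7, 37.1 and 38.3 percentage points on the sense strand against 40.5, 41.8 and 45.5 on the antisense strand.

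Adenine at base 10, the mark of piRNAs made by slicing guided by a partner piRNA that starts with U, was most frequent in sense reads. It was found in 57.2% (53.6 to 60.8%) of sense reads in A1a and 52.5% (49.9 to 55.0%) in A2d. These shares exceeded the A content of the same reads, 35.6% and 36.1%, and also the 42.9% A of the element's plus strand. In A2h the share was 48.9% (33.7 to 64.2%) over 45 reads, an interval that includes the background of 34.6%. Antisense reads had A at base 10 in 29.2% (26.4 to 32.1%) in A1a, 26.3% (24.5 to 28.1%) in A2d and 23.0% (19.98 to 26.3%) in A2h, above backgrounds of 22.6%, 19.6% and 19.6%. For antisense reads the interval reached these backgrounds under 3 of 7 other settings in A1a, 2 in A2d and 2 in A2h. Among them were 19.9% (16.8 to 23.3%) in A1a and 20.8% (18.7 to 23.1%) in A2d with only sequences of 1 place. Another was 19.6% (16.4 to 23.2%) in A2h without its strongest antisense bin. For sense reads of A1a and A2d the interval reached the background under none. The backgrounds were those of all reads and were not recomputed per setting, so a shift in base content between settings was not taken into account. The excess was 21.7 and 16.3 percentage points for sense reads of A1a and A2d, and 6.56, 6.73 and 3.46 points for antisense reads of A1a, A2d and A2h.

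**Figure D2:**
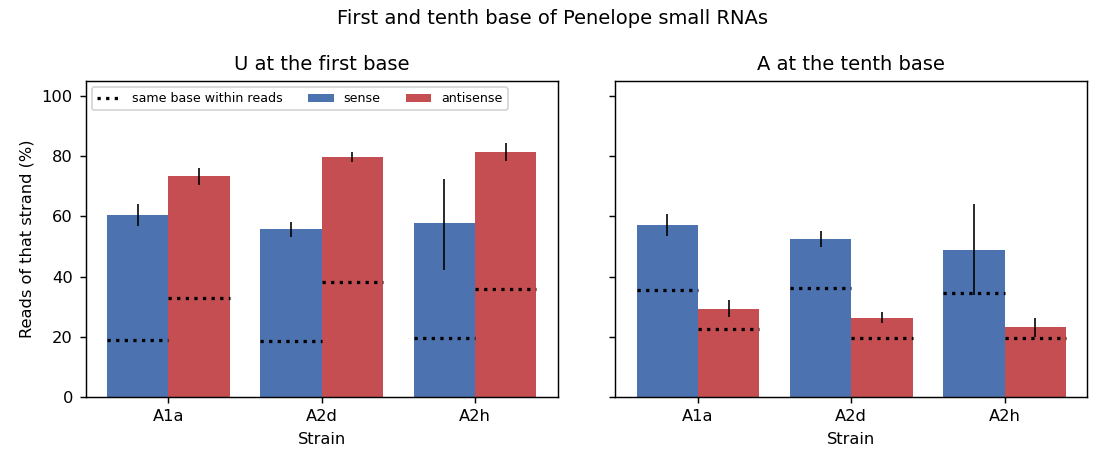
Share of reads with U at the first base and with A at the tenth base (vertical axes, percent of the reads of that strand) by strain, with exact 95% binomial intervals; dotted lines give the share of the same base at the other positions of those reads. First-base U lies above its dotted line on every strand and in every library, and tenth-base A does so most clearly in the sense reads of A1a (57.2%) and A2d (52.5%).

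Pairs of sense and antisense reads whose first 10 nt overlap, the footprint of the ping-pong cycle, were enriched in A1a and A2d and were not detected above background in A2h. In A1a the 10 nt overlap held 747 read pairs, 4.15 times the mean of 180 over the other overlaps of 1 to 20 nt, with a score of 7.11 SDs of those overlaps. In A2d it held 2621 pairs, 3.53 times the mean of 742, with a score of 7.88. It was the most frequent overlap in both libraries. With each distinct sequence counted once the excess was smaller, at 2.31 times the mean in A1a (203 against 87.9 pairs) and 2.21 times in A2d (598 against 270). In A2h the 10 nt overlap held 2 read pairs against a mean of 3.16 over the other overlaps, a score of -0.38. The score describes 1 library and has no p-value attached. Among antisense reads, 19.01% (16.6 to 21.6%) in A1a and 27.6% (25.8 to 29.5%) in A2d had a partner at exactly 10 nt, above the highest value of any other overlap, 13.3% and 21.4%. In A2h 0.284% (0.0345 to 1.02%) had one. Such shares depend on depth and on the balance of strands. Over both strands they were 18.5% in A1a, 25.1% in A2d and 0.401% (0.0828 to 1.17%) in A2h. Thinning to 748 reads without regard to strand gave 12.9% (8.96 to 16.6% for 95% of draws) in A1a and 11.9% (7.22 to 16.8%) in A2d. After thinning to the 45 sense and 703 antisense reads of A2h they were 4.26% (0.802 to 9.36% for 95% of draws) in A1a and 3.48% (0.799 to 7.75%) in A2d. The measured share of A2h lay below the ranges of draws at its strand totals, and its counting interval overlapped them. Among sense reads the share with a 10 nt partner was 17.8% (15.2 to 20.8%) in A1a and 21.3% (19.2 to 23.4%) in A2d. That was above the mean over other overlaps, 10.5% and 17.9%, but below the highest of them, 20.3% and 28.2%. By the share of sense reads with a partner, the 10 nt overlap was thus raised over the mean but was not the most frequent.

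**Figure D3:**
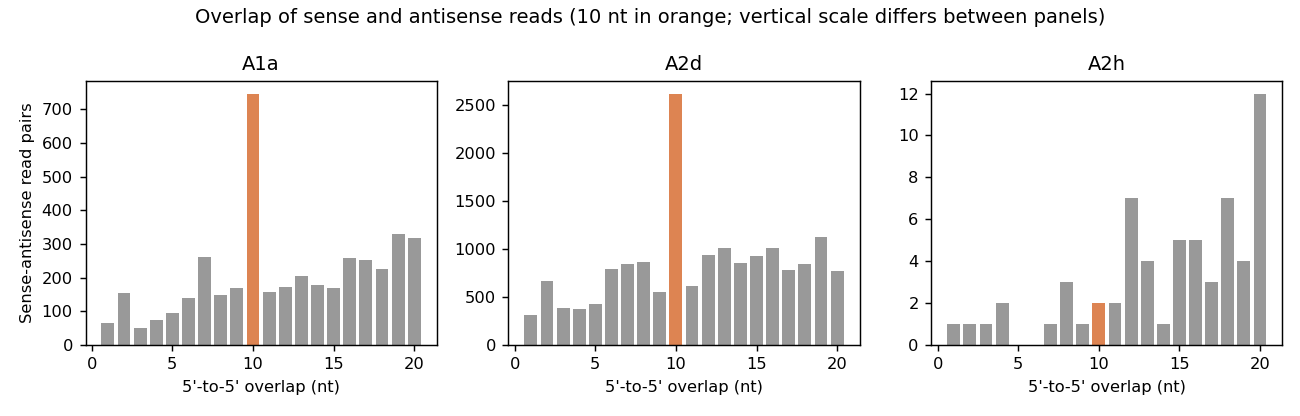
Number of sense-antisense read pairs, each pair weighted by the product of its counts (vertical axis, on a scale of its own per panel), at each 5′-to-5′ overlap from 1 to 20 nt in the 3 strains. The 10 nt overlap, in orange, stands out with 747 pairs in A1a and 2621 in A2d, and holds 2 pairs in A2h.

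The position of the reads along the element was similar in A1a and A2d and differed in A2h. Across 34 bins of 100 nt, with a read that matched both repeats counted equally at each place, Spearman's rho between A1a and A2d was 0.91 for sense and 0.91 for antisense 5′ ends. Against A2h it was 0.42 (A1a) and 0.53 (A2d) for antisense ends, and 0.54 and 0.58 for sense ends, the latter resting on 45 reads in A2h. The antisense values against A2h depended on bin size: 0.64 (A1a) and 0.63 (A2d) with bins of 50 nt, and 0.32 and 0.37 with bins of 200 nt. These are correlations across bins, which are not independent replicates, and the repeats enter at both places. Reads that matched both repeats made up 40.0% (37.0 to 43.1%) of antisense reads in A1a and 41.1% (39.1 to 43.1%) in A2d, but 9.10% (7.08 to 11.5%) in A2h. Among sense reads they made up 30.2% (26.9 to 33.6%), 26.3% (24.1 to 28.6%) and 57.8% (42.2 to 72.3%). The repeats thus held a higher share of the sense than of the antisense reads in A2h, and a lower one in A1a and A2d. The antisense reads of A2h came instead from the body of the element: 89.5% (87.0 to 91.6%) of them matched only within the open reading frame, against 54.0% (50.9 to 57.1%) in A1a and 53.0% (51.0 to 55.1%) in A2d.

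The strongest sense bin of A1a and A2d lay at positions 1101 to 1200, in the 5′ part of the reading frame, with 97 of 762 and 183 of 1523 sense reads. The next sense bins were 501 to 600 and its repeat copy at 3301 to 3400 in A1a (85.5 reads each) and 2301 to 2400 (154 reads) and 501 to 600 (119.5 reads) in A2d. In A2h the top sense bins held at most 7 reads each. On the antisense strand the first bins of A1a were 501 to 600 (109 reads), 3201 to 3300 (101.5 reads) and 1401 to 1500 (92 reads). A2d had 558 reads, 23.8% of its antisense reads, in the bin from 601 to 700, which spans the end of the left repeat and the start of the reading frame. The next antisense bins of A2d were 3301 to 3400 (217.5 reads), the repeat copy of the end of the left repeat, which largely holds the other share of the same reads, and 1401 to 1500 (156 reads). The leading antisense bins of A2h were 1401 to 1500 (147 reads), 1201 to 1300 (111 reads) and 1301 to 1400 (82 reads), neighbours that together held 48.4% (44.6 to 52.1%) of its antisense reads. The same 300 nt, positions 1201 to 1500, held 18.7% (16.4 to 21.3%) of antisense reads in A1a and 15.0% (13.6 to 16.6%) in A2d.

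**Figure D4:**
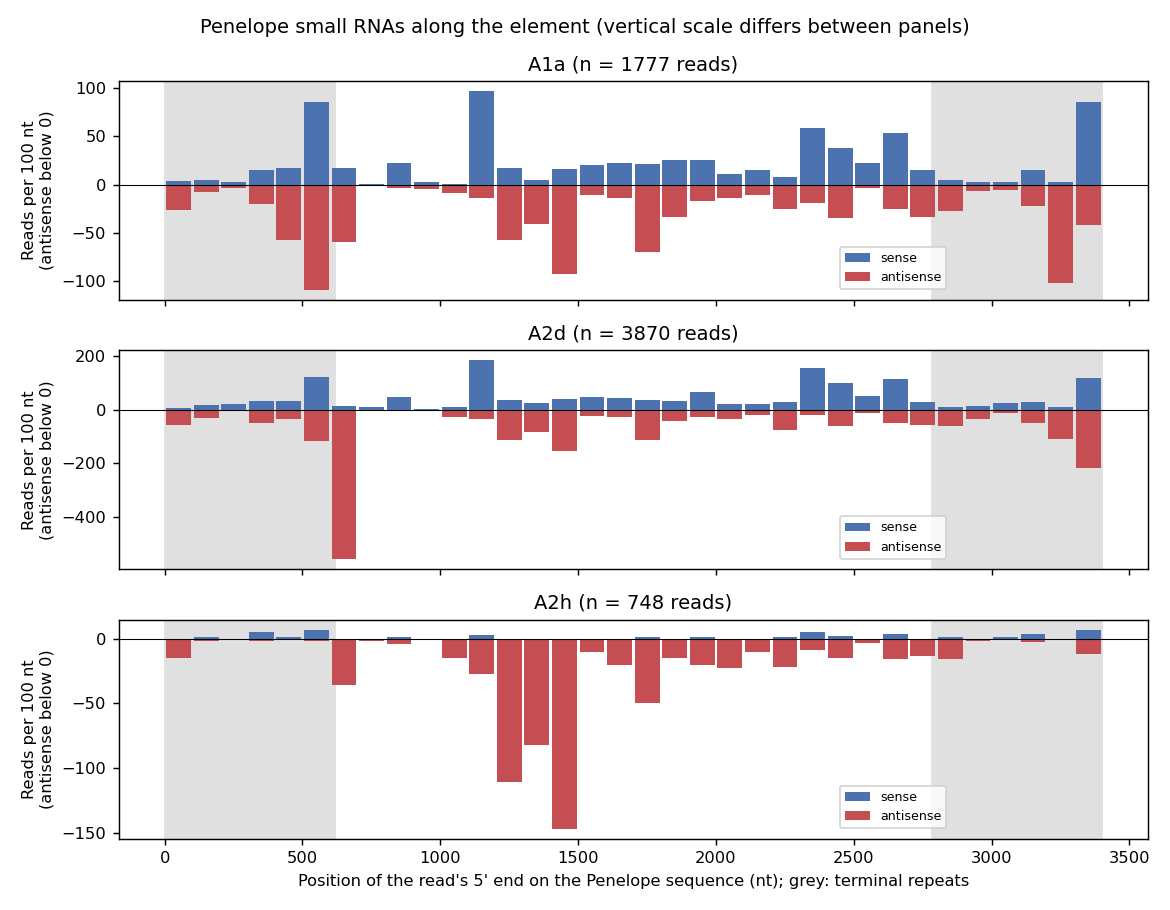
Reads per 100 nt by the position of their 5′ end on the Penelope sequence (horizontal axis, nt), sense above and antisense below 0, each strain on its own vertical scale, with the terminal repeats in grey. A1a and A2d show reads on both strands over most of the element, A2d has its strongest antisense bin at 601 to 700 (558 reads), and A2h shows almost only antisense reads, 48.4% of them between 1201 and 1500.

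The most abundant sequences reflected these profiles. In A1a the first was CATCGGCAAACCGTCTTCAGGGCAC, antisense at 491 to 515 and 3272 to 3296 in the repeats, with 42 reads in A1a, 37 in A2d and 1 in A2h. A longer form from the same place, TGCACATCGGCAAACCGTCTTCAGGGCAC, had 32 reads in A1a and 12 in A2d, and TGCACATCGGCAAACCGTCTTCAGGGC had 25 and 18, both with none listed in A2h. The sense sequence TGTTTTAACAAACACGGACCTCGAGC, at 567 to 592 and 3348 to 3373, had 40 reads in A1a and 24 in A2d and was not listed in A2h, where a count of 0 among 748 reads allows up to 3 counts. The sense sequence TACGAGATCAACGGAACCTAGCCTT, at 1128 to 1152 in the reading frame, was among the top 5 of both A1a (28 reads) and A2d (64 reads) and had 1 read in A2h. In A2d the leading sequences were 3 antisense RNAs with the same 3′ end at position 589: TTTCAATATTTATTTGTTGGCTGGCTC with 102 reads, TTCAATATTTATTTGTTGGCTGGCTC with 73 and TCAATATTTATTTGTTGGCTGGCTC with 65. They had 3, 3 and 7 reads in A1a and 7, 4 and 1 in A2h. The sense sequence ACCCATAGCCTCCGGACGAATACTC, at 2398 to 2422, had 37 reads in A2d, 10 in A1a and 2 in A2h.

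The top sequences of A2h were antisense, and 4 of the 5 lay in the reading frame between 1238 and 1437. TCCACTGTGTCCAGTATTGCTCGATCCC, at 1410 to 1437, had 18 reads in A2h, 13 in A1a and 25 in A2d, that is 2.41%, 0.732% and 0.646% of the reads. TGCTGATTGGGAGAGCGAACTTCGGCCC, at 1238 to 1265, had 16 reads in A2h against 6 in A1a and 7 in A2d. TATTGCTCGATCCCTACTGTTTTGGT, at 1398 to 1423, and TGCTCGATCCCTACTGTTTTGGTTG, at 1396 to 1420, had 11 reads each in A2h, with 2 and 4 in A1a and 10 and 9 in A2d. The remaining one, TGTACCTATGTAGACACTATTGCACT, lay in the repeats at 57 to 82 and 2838 to 2863, with 11 reads in A2h, 14 in A1a and 20 in A2d. It was among the 20 most abundant sequences of all 3 libraries, as were TCCACTGTGTCCAGTATTGCTCGATCCC and TATTGGTCTCAGTGGAGTTCCTTCCT, antisense at 1734 to 1759 with 19, 37 and 5 reads in A1a, A2d and A2h.

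Part of the small RNA repertoire was shared between strains. A1a and A2d had 383 identical sequences in common, 173 sense and 210 antisense, which held 62.1% of the A1a reads and 49.8% of the A2d reads. A1a and A2h shared 115 sequences and A2d and A2h shared 163, of which 104 and 151 were antisense. After each library was thinned to 748 reads in 200 draws, A1a and A2d shared 114 ± 6.90 sequences (SD over draws), A1a and A2h 69.9 ± 4.60, and A2d and A2h 70.9 ± 5.34. Strands were not matched in this thinning, and A2h has only 45 sense reads. Its lower numbers may therefore follow in part from its strand balance. A total of 87 sequences were present in all 3 libraries, where they held 18.1% of the A1a reads, 20.5% of the A2d reads and 36.1% of the A2h reads. No background list of sequences existed from which a chance overlap could be computed.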

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

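The mismatch column was not part of any planned comparison, and the values here were chosen after it had been seen. Counting positions from 1 on the plus strand, with the authors' Penelope base first, T580A was carried by 169 of 169 covering reads in A1a (100%, interval 97.8 to 100%), 232 of 234 in A2d (99.1%, 96.9 to 99.9%) and 10 of 11 in A2h (90.9%, 58.7 to 99.8%). The same reads match the right repeat, where they give T3361A with the same numbers. At the end of the right repeat T3395A was carried by 49 of 50 covering reads in A1a, 279 of 279 in A2d and 17 of 17 in A2h, and T3398A by 38 of 39 in A1a and 59 of 59 in A2d. Reads over T3395A can match the left repeat without a mismatch, as the A2d sequence at 589 to 614 does, so T3395A is also a difference between the repeat copies of the authors' sequence.

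The last base of the read was mismatched in 2.42% (1.76 to 3.25%) of the A1a reads and 1.76% (1.37 to 2.22%) of the A2d reads, above the mean mismatch rate per inner base of 0.945% and 0.755%. In A2h it was 1.07% (0.463 to 2.10%), an interval that overlaps its inner rate of 0.471% (0.370 to 0.591%). Position 580, where nearly all reads differ from the authors' sequence, was not left out of these rates. The inner rates are therefore not rates of sequencing or editing errors and should not be compared between libraries as such.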

How the results depend on the processing

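Of 202 values computed under another setting, 126 stayed within the counting interval of the reported value, or within 1.5 times of it for counts and scores. None of the overlap scores and rho values, the ones that could do so, changed sign. The antisense share of A2h was 91.1 to 98.4% under 7 settings, above the highest values of A1a (61.8%) and A2d (63.6%). The score of the 10 nt overlap was 3.72 to 12.7 in A1a, 5.45 to 9.61 in A2d and -0.84 to -0.23 in A2h under 6 settings. Restricting lengths to 23-29 nt moved no value beyond these limits. Thinning, fuller lists and a minimum of 2 reads change shared numbers by construction, since they change how many reads enter. For the other shifts the cause was not tested. Exact matches only, 1 place only, the left-out antisense bin and thinning to A2h were chosen after seeing the data. Depth limits the sense values of A2h, which rest on 45 reads, and no library was replicated.

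Counting each distinct sequence once put shares of 24 to 26 nt reads at 60.4% in A2d, U at base 1 of sense reads at 50.7% in A1a and 42.8% in A2d, and U at base 1 of antisense reads at 74.4% in A2d and 73.8% in A2h. It also put tenth-base A in sense reads at 49.5% in A1a, tenth-base A in antisense reads at 24.6% in A1a and 21.6% in A2d, and antisense shares at 57.6% in A2d and 91.1% in A2h. It also put scores of the 10 nt overlap at 3.72 in A1a and -0.704 in A2h, and antisense profile rho at 0.52 for A1a and A2h. Keeping only sequences with 2 or more reads put shares of 24 to 26 nt reads at 65.7% in A1a and 64.3% in A2d, U at base 1 of sense reads at 69.9% in A1a and 64.7% in A2d, and U at base 1 of antisense reads at 82.7% in A2d and 92.1% in A2h. It also put tenth-base A in sense reads at 64.0% in A1a and 33.3% in A2h, tenth-base A in antisense reads at 33.1% in A1a and 29.3% in A2d, and antisense shares at 98.4% in A2h. It also put reads with a 10 nt partner at 8.82% in A1a, 11.4% in A2d and 0% in A2h, scores of the 10 nt overlap at 12.7 in A1a and -0.229 in A2h, and read totals at 1054 in A1a, 2578 in A2d and 375 in A2h. It also put shared sequences at 34.9 for A1a and A2d, 16.9 for A1a and A2h and 17.0 for A2d and A2h. Leaving out the most abundant sequence of each library put shares of 24 to 26 nt reads at 64.4% in A2d, U at base 1 of antisense reads at 76.5% in A1a, and tenth-base A in antisense reads at 26.1% in A1a. Keeping only exact matches put U at base 1 of sense reads at 53.9% in A1a and 51.1% in A2d, tenth-base A in sense reads at 53.3% in A1a, and antisense shares at 61.8% in A1a, 63.6% in A2d and 96.5% in A2h. It also put reads with a 10 nt partner at 16.5% in A1a and 0% in A2h, and scores of the 10 nt overlap at -0.840 in A2h. Keeping only sequences with 1 place on the element put U at base 1 of sense reads at 55.5% in A1a, U at base 1 of antisense reads at 77.8% in A1a, and tenth-base A in antisense reads at 19.9% in A1a and 20.8% in A2d. It also put antisense shares at 53.4% in A1a, 55.2% in A2d and 97.1% in A2h, and scores of the 10 nt overlap at 4.49 in A1a. Leaving out the strongest antisense 100 nt of each library put U at base 1 of antisense reads at 80.7% in A1a and 76.3% in A2d, tenth-base A in antisense reads at 23.6% in A1a, 23.8% in A2d and 19.6% in A2h, and antisense shares at 51.2% in A1a and 51.0% in A2d. It also put reads with a 10 nt partner at 20.6% in A1a and 21.8% in A2d. Accepting overlaps of 9 to 11 nt put reads with a partner at 28.0% in A1a and 39.9% in A2d. Using full lists without thinning put shared sequences at 383 for A1a and A2d, 115 for A1a and A2h and 163 for A2d and A2h. Using 50 nt bins put antisense profile rho at 0.64 for A1a and A2h. Using 200 nt bins put antisense profile rho at 0.32 for A1a and A2h and 0.37 for A2d and A2h. Thinning to the strand totals of A2h put reads with a 10 nt partner at 4.26% in A1a and 3.48% in A2d. Thinning to the read total of A2h put them at 12.9% in A1a and 11.9% in A2d.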

Other observations

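The tests below were chosen after the lists had been examined, and those of the 10 nt score and the other overlaps in draws, of mismatches in A2h sense reads, of a single amplified molecule in A2d and of the bases 2 to 5 nt after the 3′ end also after the result they bear on. Antisense reads of all 3 libraries were followed on the element by U more often than U occurred within them. The base after the 3′ end was U for 56.9% (53.8 to 60.0%) of antisense reads in A1a, 53.2% (51.2 to 55.3%) in A2d and 71.5% (68.0 to 74.8%) in A2h. Within the same reads U made up 32.8%, 38.03% and 36.0%, and at 2 to 5 nt after the 3′ end it made up 34.7%, 35.6% and 45.3%. Sense reads were followed by U in 34.2% (30.8 to 37.7%) in A1a and 30.9% (28.6 to 33.3%) in A2d, against 18.8% and 18.6% within reads.

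A head-to-tail order of piRNAs, in which the next piRNA starts at the base after the last one, may underlie this pattern. The lower limit of U after antisense 3′ ends exceeded the share within reads by at least 13.2 percentage points in every library. That order predicts such an excess, but the excess is the very pattern to be explained. A preference for cutting before U predicts the excess too, so the excess does not tell the 2 apart. With reads weighted by count, antisense 5′ ends directly after a 3′ end were in excess of distances of 2 to 20 nt in A1a (score 4.39) and A2h (2.77), but the score was 1.40 in A2d, where distances of 8 and 9 nt held more. On the sense strand it was 4.71 in A1a, 4.05 in A2d and 0.18 in A2h. A few abundant sequences that happen to abut are argued against in A1a, since with each end position counted once the antisense score still reached 4.59. They are argued against less clearly in A2h. There that count gave a score of 2.67, with 50 matched ends at a distance of 1 nt against 47 at 18 nt and 46 at 17 nt. Ends in the repeats entered at both copies. Abundant sequences stay open in A2d, where that count gave 1.67 for antisense and 1.97 for sense ends. For sense ends it gave 5.85 in A1a and 0.24 in A2h. A preference of the enzyme that cuts or trims 3′ ends for a site before U, without any order between piRNAs, stays open and was not tested.

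Random loss of reads leaves the expected strand share unchanged, so depth was weighed only for the few 10 nt pairs of A2h and its missing peak. It is argued against for both only if all 45 sense reads of A2h are Penelope piRNAs. If part of them are chance matches, a possibility taken up below, the draws hold too many sense reads. No draw was made at a lower number, so depth then stays open. With A1a and A2d thinned to the sense and antisense totals of A2h, at most 0.8% of 1000 draws gave as few pairs of sequences at 10 nt as the 1 of A2h (mean 13.8 for A1a, 12.2 for A2d). The mean over the other overlaps was also lower in A2h, 2.58 against 5.32 (3.21 to 7.69 for 95% of draws) for A1a and 4.50 (2.53 to 7.21) for A2d, so part of the shortage may not be specific to 10 nt. For the missing peak the score of the 10 nt overlap, each sequence counted once, was at or below the -0.70 of A2h in at most 1.7% of draws, although at this depth it ranged widely, with 95% of draws between -0.52 and 7.50 for A1a and between -0.47 and 7.91 for A2d. In A2h 57.8% (42.2 to 72.3%) of sense but 9.10% (7.08 to 11.5%) of antisense reads matched both repeats. Drawing A1a and A2d to the same division still gave 11.4 and 9.57 pairs on average, with as few as 1 in at most 3.5% of draws. Under the same condition on the sense reads, this division is argued against as the whole cause. The mean over the other overlaps in these draws, 4.41 and 3.70, was again above the 2.58 of A2h. In these draws the 609 antisense reads of A1a with 1 place fell short of the 639 of A2h. Finer differences in position stay open and were not tested. No sense read of A2h had its 5′ end in the bins from 1201 to 1500, which held 340 of its 703 antisense reads (48.4%).

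Chance matches of other small RNAs may make up part of the few sense reads, as 40.0% (25.7 to 55.7%) of them carried a mismatch outside position 580, against 11.2% in A1a and 11.8% in A2d, and 37.8% were 23 nt long. With that position kept the shares were 48.9% (33.7 to 64.2%), 31.1% (27.8 to 34.5%) and 25.0% (22.9 to 27.3%), and the interval of A1a overlapped that of A2h. Of the 42 distinct sense sequences of A2h, 11 were also listed in A1a and 12 in A2d. U began 57.8% (42.2 to 72.3%) of its sense reads, against 60.5% in A1a and 55.7% in A2d. Small RNAs of another origin could also start with U and recur between strains, so these values do not decide. Other sources of mismatched or 23 nt sense reads were not tested. If chance matches were part of the A2h sense reads, the true sense share would be lower than the 6.02% measured. A difference between strains in the secondary pathway or in Penelope transcription stays open and cannot be separated from the single library made per strain.

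The strong antisense site of A2d at 601 to 700 held 762 reads when reads that also match the right repeat are counted in full, 32.5% (30.6 to 34.4%) of its antisense reads, against 8.97% (7.28 to 10.9%) in A1a and 6.69% (4.95 to 8.79%) in A2h. Amplification of 1 molecule is argued against, because the 762 reads belonged to 176 sequences with 43 5′ positions and the most abundant sequence held 13.4%. Reads of another locus that differs from Penelope within the stretch read are argued against as the main source. Of the 762 reads 14.7% lacked an exact match, where such a source would leave most reads without one. That share did not fall under the bound of 10% written before the test, a bound set too low given that 15.0% of all antisense reads in A2d lack an exact match. The limit of 50% used here was set after the share had been seen. A related locus identical to Penelope over this stretch would give exact matches, so it could not be tested this way and stays open. Of the 762 reads, 37.4% shared the 3′ end at position 589, as did 21.98% of 91 reads in A1a and 27.7% of 47 in A2h. A strain-specific insertion or precursor that gives rise to this site is a candidate explanation that was not tested.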
